A study of Mus musculus with 4 samples.

How the data were processed

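The series holds 4 droplet single-cell RNA libraries of mouse aorta, made with a 5′ kit from cells dissociated with collagenase, strained and freed of red cells. Per the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 6.1.1, while the matrix headers name 6.1.2. The deposited matrices hold raw UMI counts per gene and cell barcode, already restricted to barcodes called as cells by the authors. The annotation release is not given in the sources used here. The file of the cKO arch library lists 28693 features and each of the others 32285, so that library was counted against another annotation. Analyses used the 27734 gene identifiers shared by all 4 libraries, which hold 99.6, 99.5, 99.5 and 99.5% of the UMIs of the cKO arch, control arch, cKO descending and control descending library. Of the identifiers, 959 occur only in the cKO arch library, 4551 only in the others, and 1228 shared ones carry another symbol. The cKO arch file also counts a feature named RFP that is no Ensembl gene, and it is not listed in the other files. Groups were taken from the labels, with 1 library in each, and the number of animals per library is not given in the sources used here.

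Depth differed between libraries. In the same order the files hold 8634, 9283, 6813 and 6351 barcodes and 49407811, 98866674, 50922575 and 50285593 UMIs, with medians of 2694, 9554, 5445 and 5269 UMIs per barcode. Cells were kept at 500 or more genes and under 10% mitochondrial UMIs. The gene filter failed 2311, 594, 665 and 943 barcodes and the mitochondrial filter 1723, 86, 331 and 362. Doublets were scored with Scrublet in each library. Its automatic threshold called 0% of the cKO arch and 0.0160% of the control descending cells, so in every library the highest scores were removed at 0.8% per 1000 barcodes, a rule set after that result was seen. This removed 241, 597, 293 and 255 cells (4.13, 6.91, 4.97 and 4.90%).

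Counts were scaled to 10000 UMIs per cell and log-transformed, and 3000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 37 clusters, without batch integration. A cluster was named from fixed marker lists when the mean log2 ratio of a class's markers to their median over clusters reached 1.5, with at least 3 markers detected in 10% of its cells. Classes within 1 of the best score were told apart by their markers among the 10 leading genes, and a cluster stayed unnamed where these gave no clear winner or marked another class. Cluster 16 stayed unnamed for low depth with no marker of its best class among its leading genes. That score replaced an earlier version after the clusters had been seen. In all, 8 clusters stayed unnamed, holding 40.3, 12.8, 5.21 and 6.48% of the cells of each library. Clusters 2 and 4 had close smooth muscle and fibroblast scores, cluster 31 had a pericyte marker among its leading genes, and all were kept out of every class. Because they have no name, their free RNA is not covered by the rule on other classes, and levels of the genes leading cluster 2 were compared with T cell-like cells after the data had been seen. Macrophage, monocyte and dendritic clusters were joined as mononuclear phagocyte-like cells.

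For each class with at least 50 cells in both libraries, UMIs were summed and scaled to CPM by the total UMIs of the shared genes. Log2 ratios used a prior of 0.5 UMI, with exact Poisson intervals for sums, exact conditional intervals for ratios and Clopper-Pearson intervals for shares. No test was made, since each group has 1 library, and differences are described by size alone. The comparisons were cKO against control in the arch and in the descending aorta, arch against descending in each genotype, and the arch difference minus the descending difference.

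Genes were named by a rule written before the data were examined. It takes the 10 highest and 10 lowest ratios of each smooth muscle comparison among genes with at least 100 UMIs in both libraries together and 20 CPM in either, 5 of each in other classes, the 4 members of each list furthest from 0, and the first 6 contractile genes. The rule leaves out unnamed transcripts, mitochondrial, ribosomal protein, haemoglobin and immune receptor genes, genes under 0.1 of the level in another class, and genes with the same difference in fibroblast-like or endothelial-like cells, where those hold at least 0.5 of the smooth muscle level in both libraries and have at least 0.5 of the log2 ratio. The last kinds are given apart as other-cell and whole-library genes. List medians keep members of any level in other classes, but members under 0.1 of the level in another class are mostly not named as examples.

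The 25 gene lists were written at the same time. They are contractile genes, modulated smooth muscle, chondrogenic and osteogenic genes, elastic fibre assembly, collagens, proteoglycans and matricellular proteins, matrix proteases and inhibitors, TGF-beta and BMP pathway components, TGF-beta targets, BMP targets, inflammatory mediators, immediate early and dissociation genes, the unfolded protein response, the interferon response, the cell cycle, glycolysis and hypoxia, oxidative phosphorylation, mechanosensing, anterior Hox genes, posterior Hox genes, outflow tract and neural crest factors, heritable thoracic aortic disease genes, ion channels and calcium handling, vascular receptors, and markers of free RNA. For members with at least 20 UMIs the median log2 ratio was set against 10000 random lists matched on expression in 20 bins, and members at least 1.5-fold apart were counted. Lists overlap, and medians outside the central 95% are given as called.

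The comparison of RFP-high with RFP-low cells, its boundaries of 16 and 8 UMIs, the genes named from it and its 6 alternatives were all chosen after the data had been seen. So were the added settings (the automatic doublet threshold, smooth muscle with cluster 31 or with clusters 2, 4 and 31, cluster 0 alone, and RFP-high or RFP-low cells of the cKO arch library), the definition of a called result, the count of picked genes with the same direction in other classes at any level, and the choice of main results whose every moved value is printed. Another rule chosen then is that a clock test decides nothing where the members of an arm go both ways in its comparisons with the control arch library. Settings written down before any file was opened were cell filters of 200 genes with 20% and 1000 genes with 5% mitochondrial UMIs, doublets kept, resolutions of 0.5 and 2, median-of-ratios scaling, a total without mitochondrial, ribosomal protein and haemoglobin genes, a prior of 5 UMIs, list minimums of 100 UMIs and none, the mean over cells, cells thinned to 3000 UMIs, and cells with no UMI of other-class markers. A value counts as the same when it stays within its counting interval.

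The ratio code was tested on simulated data, in which UMIs were redrawn from a Poisson law around the arch and descending sums and 200 genes were shifted. In the arch, 95.9% of 13385 intervals held the true ratio, 100% of genes shifted 2-fold lay on the right side, 98% of them and 100% of genes shifted 4-fold passed 1.5-fold, and 4.87% of unshifted genes passed it. In the descending aorta, intervals held for 95.6% of 12853 genes, with 100, 99, 99 and 2.76% for the same measures. The simulation holds counting error alone, so it says nothing of variation between animals or digestions.

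Left out were features outside the shared identifiers, trajectory and cell communication analyses, and any estimate of deletion from read positions, since reads were not analysed here. Some genes that the naming rule picks are withheld and not reported here. Coordinates come from the GENCODE annotation of mm10. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.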

Results

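Cells from the whole wall of the mouse aorta were profiled with a droplet 5′ single-cell RNA assay that counts unique molecular identifiers (UMIs, 1 per captured transcript) for each gene and cell. The mice were 16 to 20 weeks old and carried CNC-SMC-Cre, a driver taken here to mark smooth muscle of cardiac neural crest origin, together with an R26-tdT reporter. In the cKO mice the driver acts on floxed Smad4, the shared signal transducer of the TGF-beta and BMP pathways, while control mice keep Smad4 intact. The arch and the descending thoracic aorta were collected for each genotype, giving 4 libraries, 1 per group. After filtering, 5601 cells of the cKO arch, 8047 of the control arch, 5608 of the cKO descending and 4951 of the control descending library were kept, with medians of 5735, 9971, 6426 and 7045 UMIs per cell. By its title the series asks whether the developmental origin of smooth muscle sets how readily it takes part in aortic disease. Y-linked transcripts such as Ddx3y were counted only in the control arch library, where Xist was counted too, as a mix of both sexes would give. Comparisons with that library therefore also differ in sex make-up. The cKO arch library alone was counted against another annotation, so comparisons with the cKO arch also differ in annotation. Because each group is a single library, none of the differences given here has a replicate check, and every interval is a 95% interval of counting error only.

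Smad4 transcripts stayed abundant in the cKO smooth muscle-like cells taken as a whole. They stood at 65.0 CPM (UMIs scaled to equal library totals) in the cKO arch (60.3 to 70.1; 697 UMIs), 72.6 in the control arch (70.14 to 75.03; 3413), 89.8 in the cKO descending aorta (85.4 to 94.3; 1569) and 92.4 in the control descending aorta (87.8 to 97.1; 1534). Over all cells Smad4 was 66.0, 77.1, 90.5 and 85.6 CPM in the same order. Reads from the 5′ end of a transcript need not show a deletion of later exons, and the floxed exons are not given in the sources used here. Smad4 is ENSMUSG00000024515, on the minus strand of mm10 chromosome 18 at 73639009 to 73703780.

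In the cKO arch library, cells with many transcripts of a feature named RFP had less Smad4 and less BMP target RNA than cells with few. RFP is taken here for the R26-tdT reporter, but its sequence is not given in the sources used here, so RFP-high need not mean recombined. RFP was high (at least 16 UMIs) in 30.0% of 887 smooth muscle-like cells, in 37.6% of 1136 cells of a cluster that was given no class name (cluster 2, led by Spp1, Comp, Tnfrsf11b, Timp1 and Igfbp2) and in 31.1% of 228 fibroblast-like cells, but in 0.310% of 1938 leukocytes. Comparing RFP-high with RFP-low cells (fewer than 8 UMIs) is a comparison within a single library, and it was chosen only after RFP had been seen in the file. If RFP marks the cells in which the driver acts, the comparison also sets cells of unlike origin against each other. No control library counts RFP.

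Smad4 was 41.4 CPM in 266 RFP-high and 71.8 CPM in 540 RFP-low smooth muscle-like cells, a log2 ratio of -0.79 (-1.10 to -0.50). The ratio was -0.70 (-0.92 to -0.48) in cluster 2, with 427 RFP-high and 611 RFP-low cells, and -1.10 (-1.78 to -0.51) in fibroblast-like cells, with 71 and 147. The Id genes, which encode inhibitors of helix-loop-helix factors and are induced by BMP, were lower in RFP-high smooth muscle-like cells, with Id1 at -1.11 (-1.39 to -0.84), Id2 at 131 against 263 CPM and Id3 at -1.03 (529 against 1084 CPM). So were the inhibitory Smads Smad6 (-0.79) and Smad7 (-0.80), the BMP receptor Smad Smad9 (-0.93) and the target Atoh8 (-0.87). In cluster 2 the ratios were -1.27 for Id1, -1.39 for Id2, -0.90 for Id3, -1.27 for Smad6 and -1.25 for Atoh8. TGF-beta targets lower in RFP-high smooth muscle-like cells included Pmepa1 (-0.91), Fn1 (-0.90) and Ccn2 (-0.73). Contractile genes were slightly higher in smooth muscle-like cells, with Acta2 at 0.11, Tagln at 0.05 and Myh11 at 0.08. Cartilage genes were lower in cluster 2, where Col2a1 had a ratio of -3.31, Cytl1 -1.94, Acan -1.50 and Comp -1.14, and Acan was lower in smooth muscle-like cells at -0.98. The immediate early genes Egr1 (1.48), Atf3 (1.23) and Fos (1.10) were higher in RFP-high smooth muscle-like cells, as were Tmem215 (3.54), Apoe (2.79), Gpc3 (2.55), the calcium pump regulator Pln (2.43) and Igfbp5 (1.95), while Rgs5 (-1.53), Pcsk5 (-1.48) and Wnt16 (-1.47) were lower. In RFP-high cells of cluster 2, Saa3 (3.78), Hhip (3.37) and the interferon gene Ifit3 (1.10) were higher and Cthrc1 (-3.41), C1qtnf3 (-3.34) and Scg2 (-2.96) lower. In RFP-high fibroblast-like cells Nrep (3.54) and Cxcl2 (3.06) were higher and Col6a5 (-6.05) and Crabp2 (-4.81) lower.

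As a list, BMP target genes had a median log2 ratio of -0.86 in RFP-high smooth muscle-like cells (10 of 13 lower by at least 1.5-fold, 1 higher), -1.21 in cluster 2 (11 of 15) and -0.60 in fibroblast-like cells (5 of 8). TGF-beta targets had -0.36, -0.50 and -0.14 in the same order, and the chondrogenic and osteogenic list -0.94, -1.10 and 0.40. Contractile genes had 0.09, outside the central 95% of matched random lists, 0.01 and -0.02. Interferon-stimulated genes had 0.37, 0.53 and -0.12, and immediate early genes 0.74 (14 of 26 higher), 0.20 and -0.05. Hand2, a factor of outflow tract tissue, was higher in RFP-high smooth muscle-like cells (0.45), and posterior Hox genes were lower (-1.61). In these cells modulated genes had -0.16 (3 higher, 3 lower), elastic fibre genes -0.32 (1 higher, 4 lower) and proteoglycans -0.22 (5 higher, 7 lower). All 3 medians lay outside the central 95% of random lists. The list of free RNA and other-cell markers had -0.13, -0.79 (10 of 16 lower) and -0.45, with the last 2 outside the central 95% of random lists, so RFP-low cells of cluster 2 and RFP-low fibroblast-like cells carried more of that RNA. Between the 2 RFP boundaries lay 81 smooth muscle-like, 98 cluster 2 and 10 fibroblast-like cells, which were left out, and calling every cell with at least 8 RFP UMIs high gave Smad4 -0.40, the BMP list -0.38 and the TGF-beta list -0.21 (3 higher, 1 lower, against 2 and 7) in smooth muscle-like cells. Cells were also thinned to 3000 UMIs, which left out the 27 smooth muscle-like, 208 cluster 2 and 687 leukocyte cells with fewer. With at least 5 RFP UMIs called high, RFP was then high in 31.7% of smooth muscle-like cells, 43.3% of cluster 2 and 2.08% of leukocytes. Their median depths over all cells were 11240, 10020 and 4039 UMIs.

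**Figure D1:**
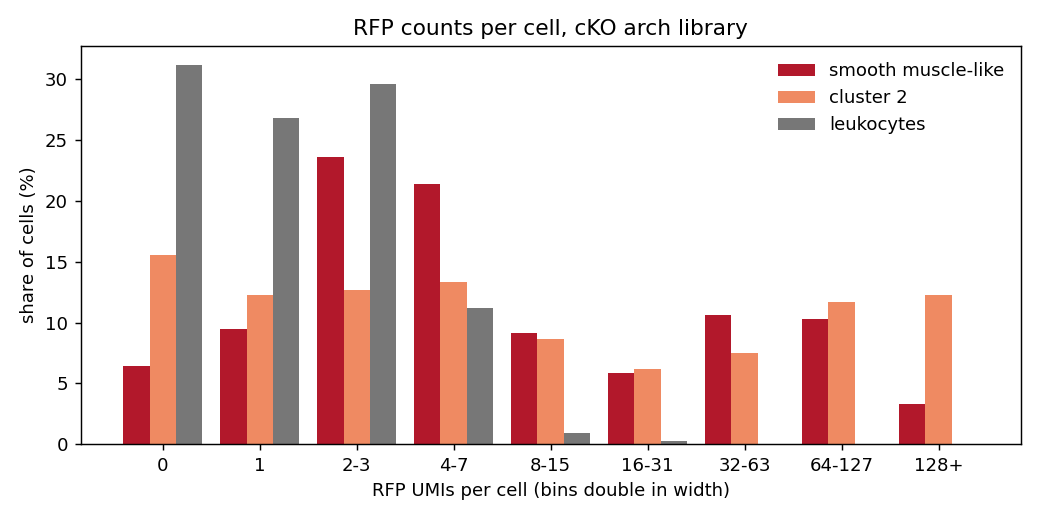
Share of cells (%) by RFP UMIs per cell, in bins that double in width, for smooth muscle-like cells, cluster 2 and leukocytes of the cKO arch library. Leukocytes lie almost wholly in the low bins, and 30.0% of smooth muscle-like cells and 37.6% of cluster 2 hold at least 16 UMIs.

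**Figure D2:**
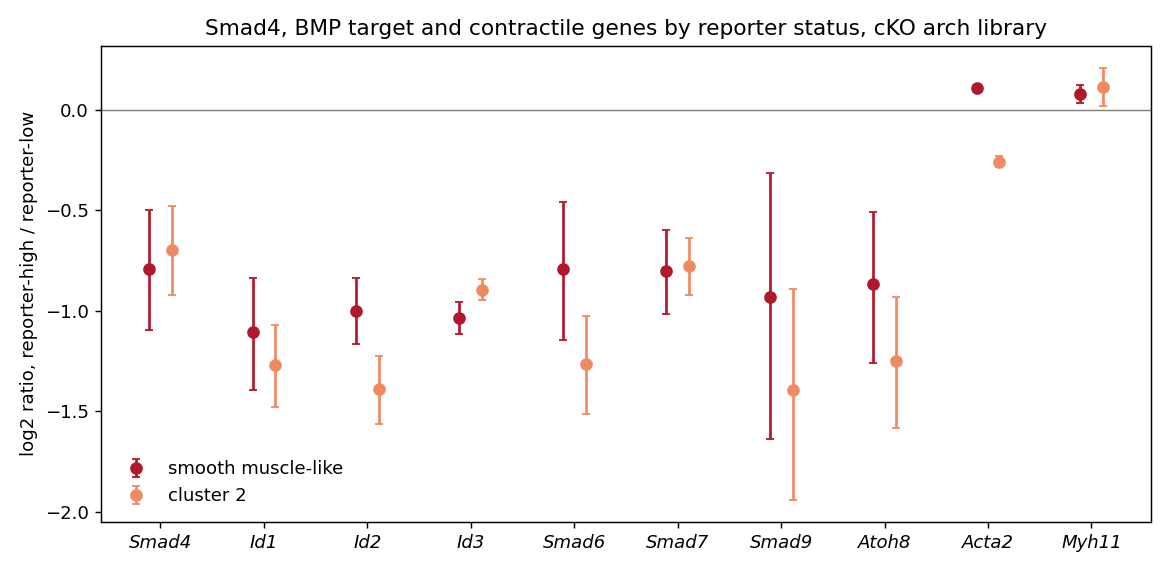
Log2 ratio of RFP-high to RFP-low cells of the cKO arch library for Smad4, BMP pathway genes and contractile genes, in smooth muscle-like cells and cluster 2, with lines for 95% counting intervals. Smad4 lies at -0.79 and -0.70, and Acta2 and Myh11 lie slightly above 0 in smooth muscle-like cells.

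Cells named smooth muscle-like, fibroblast-like and endothelial-like made up smaller shares of the cKO arch than of the control arch library, and leukocytes larger shares. The descending libraries were closer in most classes. Smooth muscle-like cells made up 15.8% (14.9 to 16.8) of kept cells in the cKO arch, 40.5% (39.4 to 41.5) in the control arch, 27.5% (26.3 to 28.7) in the cKO descending and 26.5% (25.2 to 27.7) in the control descending library. Mononuclear phagocyte-like cells made up 16.4% (15.4 to 17.4), 4.06% (3.64 to 4.52), 8.83% (8.10 to 9.60) and 10.5% (9.70 to 11.4), and the cKO arch share was 28.4% at 1000 genes and 5% mitochondrial UMIs and 25.5% at resolution 0.5. In the same order fibroblast-like cells were 4.07, 21.4, 21.3 and 18.3%, endothelial-like cells 2.77, 8.71, 16.9 and 15.6%, T cell-like cells 8.89, 1.75, 3.07 and 3.41%, neutrophil-like cells 7.46, 0.0870, 0.339 and 0.202%, and mesothelial-like cells 0.161, 3.83, 5.51 and 7.13%. Pericyte-like cells were 0.161, 0.497, 2.00 and 2.02%, lymphatic-like cells 1.05, 1.57, 4.33 and 2.83%, B cell-like cells 1.32, 0.410, 2.09 and 2.65%, Schwann-like cells 0.553, 0.572, 1.30 and 1.11%, thymocyte-like cells 0.268, 3.23, 0.0535 and 0.202%, and adipocyte-like cells 0.107, 0.0994, 0.464 and 1.17%. The descending libraries had intervals that did not overlap for fibroblast-like (20.2 to 22.4 against 17.2 to 19.4), phagocyte-like, mesothelial-like (4.93 to 6.14 against 6.43 to 7.88), lymphatic-like (3.82 to 4.90 against 2.38 to 3.33) and adipocyte-like shares (0.303 to 0.679 against 0.891 to 1.51). Cluster 2 made up 20.3% of the cKO arch library and 0.224, 0.160 and 0.0202% of the control arch, cKO descending and control descending libraries. Clusters 2 and 4 scored close for smooth muscle and fibroblast markers (2.26 and 2.95 in cluster 2). Cluster 31 scored 4.36 for smooth muscle and 2.17 for pericyte markers, but had the pericyte marker Rgs5 among its leading genes, with Msx2, Dlx5 and Dlx6. Leaving out cluster 31 removed 638 control arch and 33 cKO arch cells, and with them RNA of Rgs5 and Msx2. These clusters were kept out of every class and together were 27.8, 8.89, 0.820 and 0.586% of kept cells, with cluster 31 found almost only in the control arch (7.93%). The gap in the smooth muscle-like share between the arch libraries therefore depends on leaving them unnamed, by a rule changed after the clusters had been seen. At resolution 0.5 that share was 23.8% in the cKO arch and 42.4% in the control arch. Clusters 6 and 16, which scored best for macrophage markers, also stayed unnamed and are not in the phagocyte-like shares. Shares depend on how the tissue was taken and digested, and a cluster found mostly in 1 library may stand for that library and not for a cell state.

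**Figure D3:**
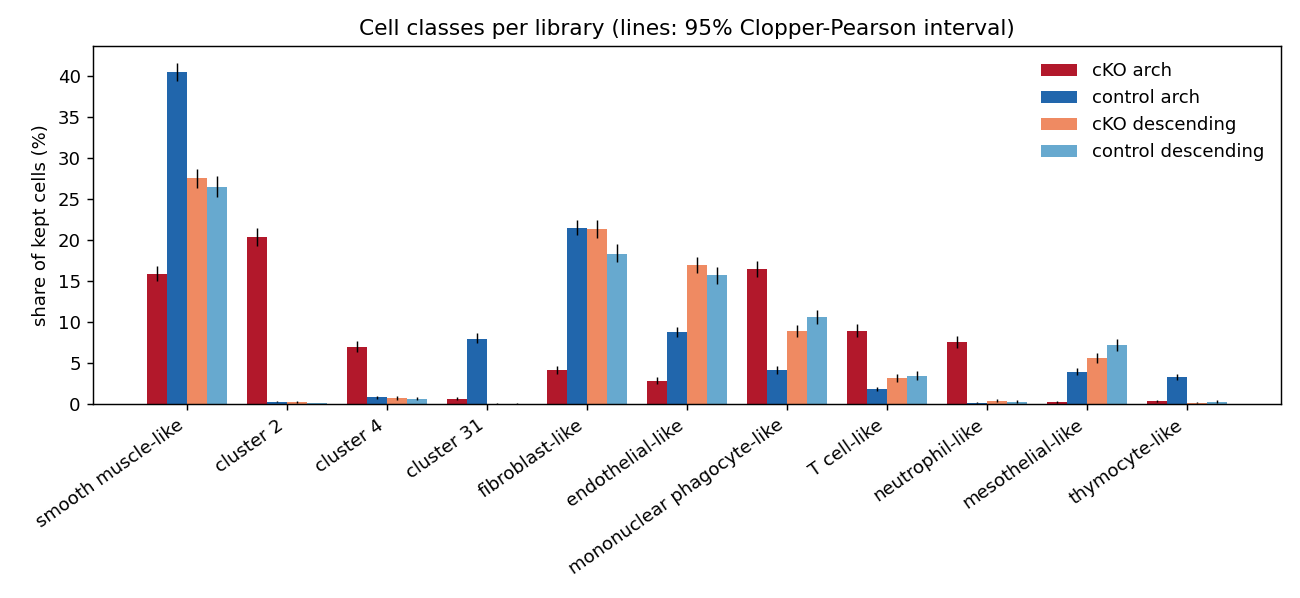
Share of kept cells (%) in each class and in the clusters kept out, for the 4 libraries, with lines for 95% Clopper-Pearson intervals. Cluster 2 stands at 20.3% in the cKO arch library and below 1% in the other libraries.

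In the arch, smooth muscle-like cells of the cKO library had more RNA of modulated smooth muscle genes than those of the control library, and more of inflammatory mediators, as did other classes of that library, while contractile genes were close to level. Igfbp2, which binds insulin-like growth factors, stood at 479 against 39.0 CPM, a log2 ratio of 3.62 (3.54 to 3.70), and the cartilage matrix gene Comp at 105 against 12.1 CPM, 3.11 (2.96 to 3.26). Cardiac actin, Actc1, was lower, with 8 against 1291 UMIs and a ratio of -5.11 (-6.42 to -4.22), as was the sodium-calcium exchanger Slc8a1 (-2.97). Actc1 also marks heart muscle and belongs to the list of free RNA markers. The comparison sets 887 against 3256 cells. Cluster 0 holds 87.1% of the cKO class and cluster 3 holds 62.7% of the control class.

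Other genes higher in the cKO arch cells were the adenylyl cyclase Adcy1 (115 against 1.81 CPM, 5.98), Rgs17 (4.79), Tlcd2 (4.10), the clock repressor Nr1d1 (3.24), Tent5b (3.04), slow skeletal troponin Tnnt1 (2.86) and the guidance factor Sema3e (2.68). Lower were Kctd16 (0.560 against 21.9 CPM, -5.18), Nfil3 (-3.11), Igsf9b (-3.09), Galnt2 (-2.55), Ptges3l (-2.10) and Nrep (-2.09). A Ccl19 copy (-3.73) belongs to a family of near-identical genes, so its value is uncertain. Dbp (4.20), Nr1d2 (3.13), Col8a1 (36.5 against 4.57 CPM) and Cwc22 (-2.83) had the same direction in fibroblast-like or endothelial-like cells and stand for the whole library. Of the 20 genes picked for smooth muscle-like cells, 11 also had that direction in at least 1 of those classes, with an interval away from 0 and at least 0.5 of the size. They include Nr1d1 (4.66 in fibroblast-like and 3.96 in endothelial-like cells), Nfil3 (-1.68 and -2.73), Slc8a1 (-3.40 and -2.06) and Galnt2 (-1.91 and -3.05), so these are not particular to smooth muscle. The 11 also include Igfbp2 and Comp, which count through levels near that of T cell-like cells, as free RNA of cluster 2 gives, so the count may be too high. Genes with few UMIs in those classes may be missed, such as Kctd16 in fibroblast-like cells (0 against 21 UMIs, -2.61, with an interval that spans 0). Mmp3 (5.91), Fbln2 (1.94), Cd74 (1.94), Fbln1 (-3.20) and Spon1 (-2.97) are more abundant in other classes, and free RNA of those cells can reach smooth muscle droplets.

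The median log2 ratio over all genes was -0.12, and median-of-ratios scaling shifts every value by 0.13. Modulated smooth muscle genes had a list median of 0.98 (11 of 20 higher by at least 1.5-fold, 0 lower), with Spp1 at 5.52. List medians keep members that are far more abundant in another class, so free RNA can enter them. Spp1, Comp and Igfbp2 are leading genes of cluster 2, and its free RNA reaches other droplets of the cKO arch library. Spp1 stood at 0.241 UMIs per cell in smooth muscle-like and 0.217 in T cell-like cells of that library, so its ratio is not a property of smooth muscle, while Comp stood at 1.26 and 0.303 and Igfbp2 at 5.79 and 0.241. Inflammatory mediators had 1.05 (13 of 23 higher). The same list was at 0.73 in endothelial-like, 0.59 in fibroblast-like and 1.43 in phagocyte-like cells, and the share of free RNA in its members was not measured, so it is not tied to smooth muscle. Interferon-stimulated genes had 0.28 (10 of 24 higher). Posterior Hox genes had 0.97, from 5 measured members such as Hoxa7 (67 against 49 UMIs, 2.58) and Hoxa5 (0.78). The chondrogenic and osteogenic list had 0.27, with Comp higher and Sox9 (-1.94) and Alpl (-2.35) lower, and vascular receptors 0.11, with Agtr1b (3.67) and P2rx1 (2.17) higher and Adra1d (-1.79) lower. Those medians turned sign under 5 and 6 of the settings fixed in advance, down to -0.35 and -0.27 with at least 100 UMIs per gene, so no direction is given for either list. Lower were elastic fibre genes (-0.34; 9 of 23 lower, among them Mfap5 at -1.88), immediate early genes (-0.31), glycolysis and hypoxia genes (-0.29; Adm -1.86) and heritable thoracic aortic disease genes (-0.25; Prkg1 -0.93 and Lox -0.74). These 10 medians lay outside the central 95% of 10000 random lists matched for expression.

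The other 15 lists lay inside that range. Contractile genes had -0.14 (6 of 30 lower), with Acta2 at -0.09, Myh11 at -0.43, Cnn1 at -0.31, Des at -0.95 and Pln higher at 1.14. BMP targets had -0.27 (Id2 0.54, Id4 -1.52), TGF-beta and BMP pathway components -0.17 (Bmpr1b -1.52), TGF-beta targets -0.05, collagens -0.16 (Col14a1 -1.35), proteoglycans 0.02 (Tnc 2.44) and matrix proteases and inhibitors 0.08 (Plat 1.57). The unfolded protein response list had -0.00 (Ddit3 0.80), cell cycle 0.03, oxidative phosphorylation 0.09, mechanosensing -0.05 (Itga1 -1.16), anterior Hox genes -0.21, outflow tract and neural crest factors -0.11, ion channels and calcium handling -0.28 (Kcnma1 -1.23) and markers of free RNA -0.30. Gata4, an outflow tract factor, had 0 UMIs in the cKO and 212 in the control cells. Thymocyte-like cells were 0.268% of the cKO and 3.23% of the control arch library, and fibroblast-like cluster 17 held 0 and 166 of their cells. For Gata4, Actc1 and the posterior Hox genes, genotype and the extent of tissue taken therefore cannot be told apart. Within cluster 0 alone the modulated list was 0.35 and the chondrogenic list, immediate early list and receptor list turned to -0.11, 0.28 and -0.38. Cluster 0 holds only 5.44% of the control arch class, cells grouped with cKO cells by their expression, so smaller differences within it are built in. Adding clusters 2, 4 and 31 to the class gave 3.77 for the modulated and -0.87 for the contractile list and turned the disease gene list to 0.03.

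**Figure D4:**
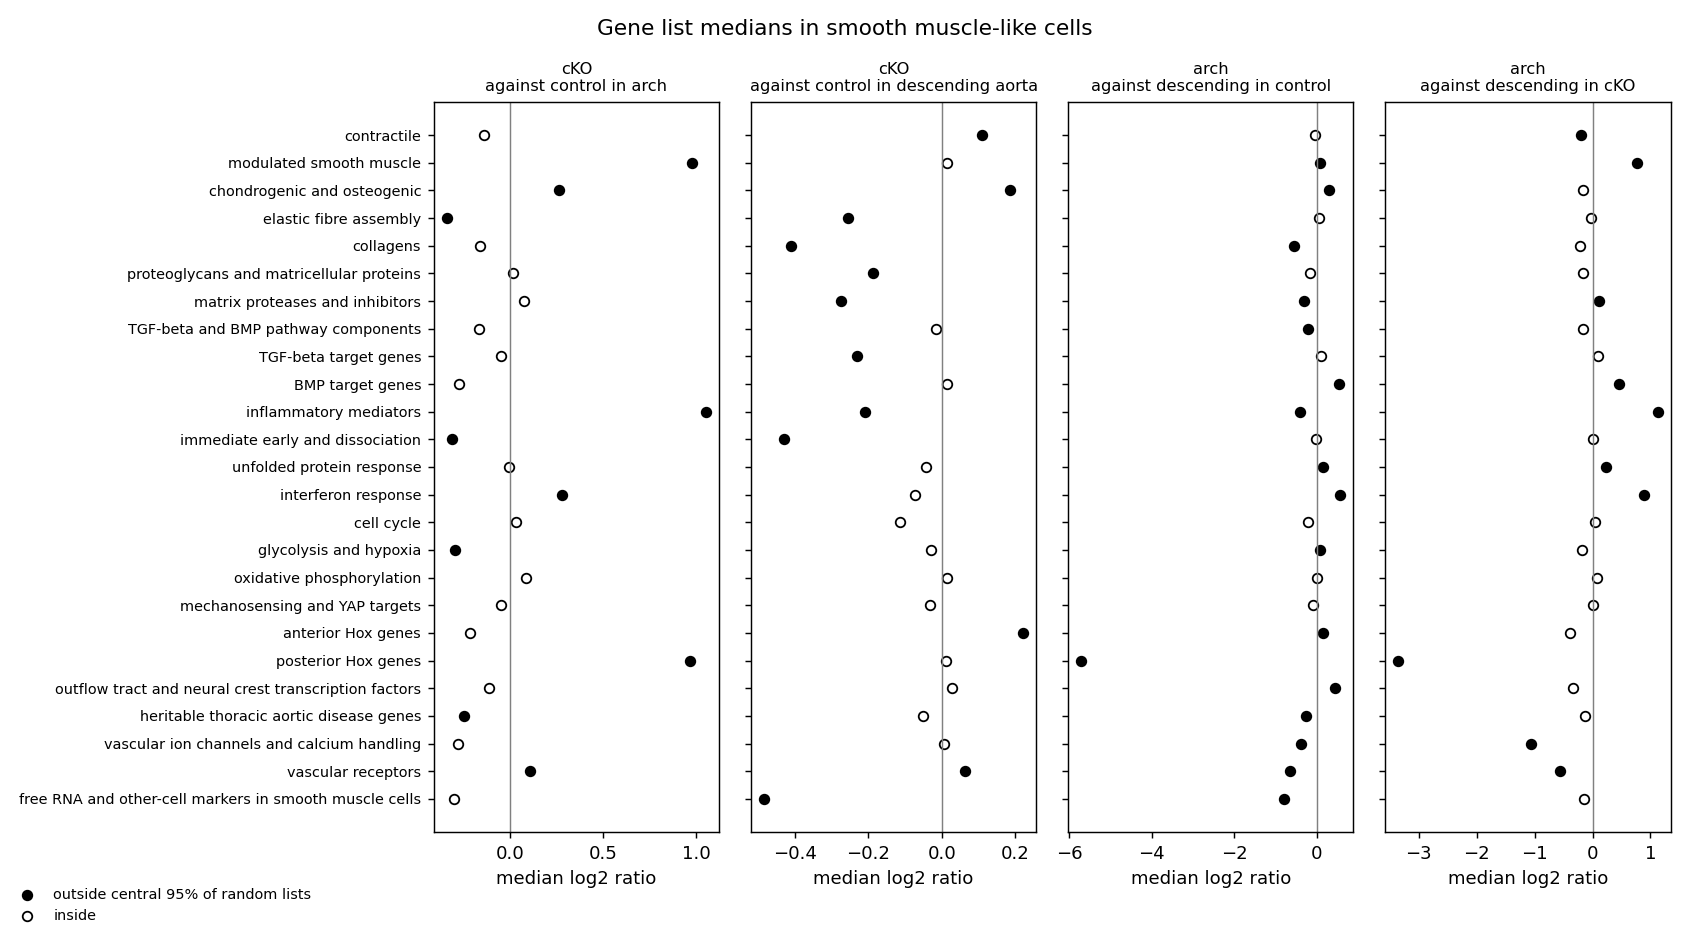
Median log2 ratio of each of 25 gene lists in smooth muscle-like cells, in 4 panels with their own scales: cKO against control in the arch and in the descending aorta, and arch against descending in control and in cKO. Filled points lie outside the central 95% of matched random lists; posterior Hox genes stand at -5.71 between control regions, and modulated genes at 0.98 in the arch.

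In the descending aorta, smooth muscle-like cells of the cKO library had less elastin and collagen RNA than control cells, with contractile genes slightly higher and modulated genes going both ways. The descending aorta was taken here as tissue outside the territory that the driver would mark, and Smad4 stood at 89.8 against 92.4 CPM. Loss of Smad4 therefore cannot be told apart from differences between animals or libraries in these values. Eln, the elastin gene, stood at 2017 against 4418 CPM, a log2 ratio of -1.13 (-1.15 to -1.11). Vwc2, a secreted BMP-binding protein, had 1643 UMIs in the cKO and 1 in the control cells (10.02; 8.13 to 15.91), and the GABA receptor subunit Gabra3 had 1450 and 7 (7.52; 6.57 to 8.94). The comparison sets 1541 against 1310 cells, with clusters 1, 5, 0 and 28 holding most of both groups. The median over all genes was -0.03.

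Higher in the cKO descending cells were Stbd1 (127 against 25.1 CPM, 2.34), Sema3e (1.95), Adcy1 (66.8 against 27.8 CPM, 1.26), the sphingosine phosphate receptor S1pr3 (0.88), the plasminogen activator Plat (0.81) and the G protein regulator Rgs5 (0.74). Lower were Bche (-1.85), Casq1 (37.0 against 92.2 CPM, -1.32), Gipc2 (-1.01), Sel1l3 (-1.01), the sterol genes Sqle (-0.98) and Cyp51 (-0.91) and Mt2 (-0.93). Rnaset2b (-3.30) was lower in every class compared, with -4.11 in fibroblast-like, -3.56 in endothelial-like and -4.44 in phagocyte-like cells. It has the near-identical neighbour Rnaset2a (0.60), so reads of the pair are uncertain. Scarb2 (0.87), Sparc (-1.01), Lox (-0.86), Col3a1 (-0.79), C1qtnf6 (-1.16) and Pdgfrl (-1.14) had the same direction in other classes. By the measure used for the arch so did 10 of the 20 picked genes, among them Stbd1 (2.52 in fibroblast-like and 2.89 in endothelial-like cells) and, in fibroblast-like cells, Eln (-1.32). Car3 (-4.36), Ucp1 (-3.85) and Cox8b (-3.77) are adipocyte genes that were lower with the smaller share of adipocyte-like cells.

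Among the lists, contractile genes had 0.11 (1 of 30 higher), with Tagln at 0.17 and Acta2 at 0.12. Modulated genes had 0.01 (3 of 19 higher, 3 lower). Elastic fibre genes had -0.26, with Eln and Lox lower, collagens -0.41 (6 of 20 lower, Col4a5 at -0.76 among them), TGF-beta targets -0.23, proteases -0.27, proteoglycans -0.19, inflammatory mediators -0.21 (Ptgs2 -1.15) and immediate early genes -0.43 (Nr4a1 -0.73). BMP targets stood at 0.01. Restricted to cluster 0, the contractile list was -0.022 and Bche turned to 0.56, and with clusters 2, 4 and 31 added the inflammatory list was 0.002. Ttn, titin, was at -1.35 but turned sign under 5 other settings.

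Taking the arch difference minus the descending difference, the ratios between genotypes differed in size between the regions. The other annotation of the cKO arch library cannot be separated from genotype and region in these values. Slc8a1 and Galnt2, given below, were also lower in fibroblast-like and endothelial-like cells of the cKO arch than of the control arch. Some genes were higher in both cKO libraries by unlike amounts, such as Adcy1 (5.98 and 1.26), Sema3e (2.68 and 1.95) and Vwc2 (2.38 and 10.02). The differences were 4.72 for Adcy1, 4.30 for Igfbp2 (3.62 in the arch and -0.69 in the descending aorta), 4.28 for Rgs17, 3.10 for Tent5b, 3.08 for Nr1d1, 2.85 for Tnc and Tnnt1, 2.77 for the ATP receptor P2rx1, 2.68 for Gipc2 and 2.63 for Comp. Toward lower values in the arch were Vwc2 (-7.65), Actc1 (-6.92), Gabra3 (-5.60), Kctd16 (-4.70), Igsf9b (-2.84), Slc8a1 (-2.78), Bche (-2.75) and Galnt2 (-2.29). For Vwc2, Gabra3 and Nr1d1 the cKO libraries were close, with arch against descending ratios of 0.15, -0.04 and 0.29. Between the control libraries these ratios were 7.8, 5.56 and -2.8. The differences of these genes therefore come mainly from the control libraries, and need not mean that genotype acts unlike in the regions. Modulated genes had 1.02, inflammatory mediators 0.63, interferon-stimulated genes 0.51, TGF-beta targets 0.33 and collagens 0.32, while the ion channel list had -0.53, contractile genes -0.20 and BMP targets -0.07. With cluster 0 as the whole class the modulated list turned to -0.32 and the ion channel list to 0.02, with RFP-high cells alone the TGF-beta list turned to -0.07, and with doublets kept the modulated list was 0.31.

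Between regions, control smooth muscle-like cells of the arch and the descending aorta differed strongly in genes of body position. Hand2 stood at 74.4 against 0.723 CPM, a log2 ratio of 6.63, and the posterior Hox genes, which pattern the trunk, had a list median of -5.71 (11 of 11 lower), with Hoxa7 at -5.90 and Hoxb7 at -5.71. The chondrocyte factor Sox9 (28.5 against 3.25 CPM, 3.12) and cardiac troponin Tnnt2 (74.95 against 13.13 CPM, 2.51) were higher in the arch, and tenascin C, Tnc, was lower (14.1 against 152 CPM, -3.44). The median over all genes was -0.13. Cluster 3 holds 62.7% of the control arch and 1.83% of the control descending class, and cluster 1 holds 14.4 and 45.2%. Values between these regions therefore also carry which clusters make up the class.

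Also higher in the control arch were Vwc2 (7.79; 5.90 to 13.68; 943 against 1 UMI), Gabra3 (5.56), Psd (3.97), Actc1 (3.29), Nfil3 (3.18), Slc25a34 (2.39) and the vasodilator peptide gene Adm (2.27). Lower were Sema3a (-4.03), Adcy1 (-3.94), the odorant receptors Olfr78 (-3.26) and Olfr558 (-2.64), Slc22a3 (-3.01), P2rx1 (-2.94), Nr1d1 (-2.79) and Enpep (-2.70). Olfr78 and Olfr558 are leading genes of cluster 28, which holds 2.40% of the control arch and 8.93% of the control descending class. Arntl (3.54) and Dbp (-5.24) were apart in the same direction in other classes. So were 10 of the 20 picked genes, among them Nr1d1 (-4.63 in fibroblast-like and -3.53 in endothelial-like cells), Nfil3 (2.93 and 2.40) and, in fibroblast-like cells, Tnnt2 (4.56). BMP targets had 0.54 (6 of 13 higher, with Smad6 at 1.33), interferon-stimulated genes 0.57, outflow tract factors 0.44, vascular receptors -0.65 (Agtr1b -4.02), collagens -0.54 (Col8a1 -1.65), inflammatory mediators -0.41, ion channels -0.39 (Cacna1h -2.13, Kcna5 -2.05) and proteases -0.30. The outflow tract list turned to -0.061 with members of at least 100 UMIs, a setting fixed in advance, and to -0.011 in cells of cluster 0, so no direction is given for it, and the posterior Hox list was -4.20 in cluster 0.

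Between regions in cKO mice, Hand2 again stood high in the arch (65.0 against 0.572 CPM, 6.76; 5.94 to 7.90) and posterior Hox genes low (-3.35; 9 of 10 lower). Igfbp2 stood at 479 against 10.5 CPM (5.51), and the odorant receptor Olfr78 (-5.05) and Rgs5 (105 against 833 CPM, -2.99) were lower in the arch. The median over all genes was -0.19, and median-of-ratios scaling shifts every value by 0.19. Sphkap (4.97), Tlcd2 (4.06), Tnnt2 (2.88), Rgs17 (2.65), Tnnt1 (2.64), aggrecan, Acan (2.36), and Maff (2.31) were higher in the arch, and Olfr558 (-4.74), Nrip2 (-4.43), Igsf9b (-3.86), S1pr3 (-3.70), Sema3a (-3.39) and Ldb2 (-2.97) lower. Olfr78, Olfr558, Nrip2 and S1pr3 are leading genes of cluster 28, which holds 1.35% of the cKO arch and 12.9% of the cKO descending class. Cluster 0 holds 87.1 and 16.1%, so values between these regions also carry the make-up of the class. Modulated genes had 0.77, inflammatory mediators 1.12, interferon-stimulated genes 0.90, BMP targets 0.45 (Tbx20 1.90, Smad6 0.91), ion channels -1.06 (14 lower; Slc8a1 -2.74, Kcna5 -2.52) and receptors -0.56 (Ptger3 -3.23). Of the 20 picked genes, 12 had the same direction in fibroblast-like or endothelial-like cells, a count that free RNA can raise, as with Igfbp2. With only the RFP-high cells of the cKO arch library, the BMP list turned to -0.18.

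Subclustering the smooth muscle-like cells alone set the arch libraries apart, while 5 of the 9 subclusters were mixed. In subclusters 0, 4, 5 and 6 a single library made up 95.4, 99.8, 98.9 and 99.6% of the cells, and in the others the largest library made up 43.5 to 57.2%. Subcluster 0 took in 93.7% of the cKO arch cells, subclusters 4, 5 and 6 held 13.6, 48.0 and 17.0% of the control arch cells, and subcluster 8 held 47.3% of the cKO and 41.0% of the control descending cells. Subcluster 1, led by stress genes and Neat1, held 3.04, 15.7, 21.2 and 23.7% of the cKO arch, control arch, cKO descending and control descending cells. A subcluster made mostly of 1 library cannot be told from that library's own conditions.

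In other classes of the arch, phagocyte-like cells of the cKO library carried more RNA of inflammatory and interferon genes than those of the control library. Il12b had 266 UMIs in cKO and 0 in control phagocytes. Their inflammatory list had 1.43 (19 of 24 higher), interferon-stimulated genes 0.94 and BMP targets 1.18. Cluster 7 holds 72.0% of the cKO and cluster 12 holds 72.5% of the control phagocytes, so these values also carry which clusters make up the class. In fibroblast-like cells Chl1 (6.42), the retinoic acid carrier Crabp2 (5.40), Col6a5 (4.43) and Ltc4s (4.33) were higher in the cKO arch, and Cxcl13 (-5.00) lower. Their BMP target list had -0.88 (9 of 15 lower) and their chondrogenic list -1.17 (11 of 17 lower). Cluster 17, led by Chad and Tbx20, holds 166 of the control and 0 of the cKO arch fibroblast-like cells, so these values include that cluster, and the lists were not measured without it. In endothelial-like cells Ddah1 (3.42), Ltbp2 (3.02) and Ccn2 (2.89) were higher and Esm1 was at 0 against 100 UMIs, with list medians of 1.09 for modulated, 0.73 for inflammatory and 0.66 for collagen genes. Free RNA of cluster 2 can enter these values. Its leading genes Spp1 and Ltbp2 stood at 0.587 and 0.503 UMIs per cell in endothelial-like and 0.217 and 0.0864 in T cell-like cells of the cKO arch.

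In the descending aorta, phagocyte-like cells of the cKO library had less inflammatory RNA than those of the control library (list median -0.74), with the scavenger receptors Marco (-4.33) and Olr1 (-3.90) and Apoc1 (-4.66) lower and Clec9a (2.45) higher. Cluster 35, led by Alox15, Saa3 and Prg4, holds 23.6% of the control and 3.23% of the cKO phagocyte-like cells, so these values also carry the make-up of the class. Klk1 had 144 UMIs in cKO and 0 in control phagocytes. In fibroblast-like cells Gabra3 (2.97), Mmp3 (2.37) and Pax1 (1.42) were higher and Thbs4 (-1.60) lower. In endothelial-like cells Coch (2.83), Col23a1 (2.01) and Sulf2 (1.84) were higher and Rbp4 (-2.62) lower, with a list median of -0.56 for oxidative phosphorylation genes (11 of 28 lower).

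Coordinates of the main genes on mm10 are as follows. Hand2 is ENSMUSG00000038193 (chromosome 8, 57320983 to 57324633, plus strand), Igfbp2 ENSMUSG00000039323 (chromosome 1, 72824503 to 72852474, plus) and Comp ENSMUSG00000031849 (chromosome 8, 70373558 to 70382066, plus). On the minus strand lie Actc1, ENSMUSG00000068614 (chromosome 2, 114047282 to 114053548), Eln, ENSMUSG00000029675 (chromosome 5, 134702593 to 134747323), Hoxa7, ENSMUSG00000038236 (chromosome 6, 52214491 to 52221854), Gabra3, ENSMUSG00000031343 (chromosome X, 72432681 to 72656848), and Nr1d1, ENSMUSG00000020889 (chromosome 11, 98767932 to 98775333). On the plus strand are Id1, ENSMUSG00000042745 (chromosome 2, 152736251 to 152737410), Id3, ENSMUSG00000007872 (chromosome 4, 136143497 to 136145755), Sox9, ENSMUSG00000000567 (chromosome 11, 112782224 to 112787760), Vwc2, ENSMUSG00000050830 (chromosome 11, 11114223 to 11268931), and Spp1, ENSMUSG00000029304 (chromosome 5, 104435118 to 104441050).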

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

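For the patterns in this part, the tests of dissociation and of free RNA were written before their values were seen, and all other tests were chosen only after the result was seen.

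In smooth muscle-like cells, several results between genotypes had opposite signs in the arch and the descending aorta, which is what singled them out. The inflammatory list was 1.05 in the arch and -0.21 in the descending aorta, a gap of 1.26 between medians, while the median of the differences over the 17 members measured in both was 0.63. Igfbp2 was 3.62 and -0.69 (gap 4.30), Gipc2 1.67 and -1.01 (gap 2.68), and P2rx1 2.17 and -0.60 (gap 2.77). Actc1 was -5.11 and 1.81 (gap -6.92), S1pr3 -1.16 and 0.88 (gap -2.04), and Rgs5 -0.73 and 0.74 (gap -1.46). S1pr3 is a leading gene of cluster 28, which holds 1.35% of the cKO arch, 2.40% of the control arch, 12.9% of the cKO descending and 8.93% of the control descending class. The S1pr3 values therefore also carry the make-up of the class. Rgs5 is a leading gene of cluster 31, which was kept out of the class. Each group is 1 library, so the difference was not tested for any of them, and the descending value of Actc1 turned to -0.87 under the stricter cell filter. No group is large enough for a test of outlying libraries.

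BMP target genes were lower in RFP-high than in RFP-low cells of the cKO arch library, with medians of -0.86 in smooth muscle-like cells and -1.21 in cluster 2, and so were markers of free RNA and other cells at -0.79 in cluster 2 (-0.13 in smooth muscle-like cells), so RNA of other cells was not excluded there. Depth is argued against, because the higher of the 2 medians was still -0.81 with RFP status set at a fixed depth. It was -0.99 among cells with a Hand2 UMI and no posterior Hox UMI, whose immediate early list was 0.86 in smooth muscle-like cells and 0.39 in cluster 2. That argues against a mix of arch and descending positions, as far as these genes mark them, but position within the arch was not tested. A dissociation response, position within the arch, a difference between cells of unlike origin and loss of Smad4 signalling cannot be told apart. If RFP is the reporter, it marks the cells in which the driver acts. No control library counts RFP, so origin and loss of Smad4 go together here. Among cells of low immediate early share the higher median was -0.43, that of smooth muscle-like cells (88 RFP-high and 310 RFP-low left), between the values set for either outcome. The immediate early list of these smooth muscle-like cells was 0.03, and Smad4 was -0.64 in them and -0.68 in cluster 2. Cluster 2 kept -0.96, but its immediate early list was 0.24 under that restriction and 0.20 before it, so that value decides nothing, and fibroblast-like cells, which this test left out, had -0.60 with the immediate early list at -0.05. That recombined cells have lost Smad4-dependent BMP transcription is a hypothesis that takes RFP for the tdT reporter, which no source used here states. A count of recombined Smad4 alleles per cell in replicate animals, with RFP also counted in control libraries, would test it.

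Modulated smooth muscle genes were higher in smooth muscle-like cells of the cKO arch than of the control arch, with a list median of 0.98. The same list was at 1.09 in endothelial-like cells, so a difference of the whole library, of which free RNA can be a part, may account for it. Within cluster 0 alone it was 0.35. Clusters were made from the same expression values, and cluster 0 holds 87.1% of the cKO and 5.44% of the control arch class. Control cells in it were thus picked for likeness to cKO cells, so that fall decides nothing about the make-up of the class. Free RNA of other cells and RNA of the smooth muscle-like cells themselves cannot be told apart, since the lowest level in 4 other classes made up a median of 0.399 of the excess, from 0.0488 for Fn1 to 2.07 for Ly6a. Within the cKO arch library the list was -0.16 in RFP-high against RFP-low smooth muscle-like cells (3 higher, 3 lower). It was 0.04 when every cell with at least 8 RFP UMIs was called high, so these values do not tie the list to RFP-high cells. What stays open is whether any part belongs to the cKO smooth muscle, and replicate libraries with empty droplets counted would tell.

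Clock genes stood apart in the control arch library, where Arntl was high and Dbp and Nr1d1 were low. A change of annotation is argued against by a spread of 6.30 between the arms of the clock against the control descending library, which shares its annotation. Region as the whole account is argued against in smooth muscle-like, fibroblast-like and endothelial-like cells, where the cKO spread between regions was at most 0.311 of the control spread. A part from region stays open, because between cKO regions the arm of Dbp had medians of -0.96, -1.21 and -0.39 in that order. In each of these classes members of at least 1 arm went both ways between cKO regions. The spread was at least 4.46 in those classes against both neighbouring libraries. Collection at another time of day would give that, but the same comparisons singled out the pattern, so they are no test of it. The time of collection is not given in the sources used here. In phagocyte-like cells region and time of day cannot be told apart, although the cKO spread was 0.866 of the control spread. The arm of Dbp was lower in the arch of both genotypes (0 of 5 and 1 of 6 members higher), as a region difference would give, but that of Arntl went both ways (3 of 4 and 2 of 4 higher), and both arms did so between the arch libraries, where the smallest spread was 0.208.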

How the results depend on the processing

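No paired analysis was possible because each group holds 1 library and no pairing is labelled, so no test was run under any setting. Of gene ratios under settings fixed in advance, 5311 stayed the same, 1060 moved and 22 turned sign; of list medians 1232, 369 and 24; of class shares 35, 45 and 0; of subcluster shares 5, 3 and 0. Under settings chosen after seeing the data the counts were 1996, 981 and 45 for genes, 400, 263 and 20 for lists, and 11, 5 and 0 for shares. Every turned value and every moved value of the main results follows, and the cause was not tested for any of them. Depth limits the genes with few UMIs most.

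At 1000 genes and 5% mitochondrial UMIs, smooth muscle-like shares were 19.5% in cKO arch, 43.7% in control arch, 30.6% in cKO descending and 31% in control descending, while phagocyte-like shares were 28.4% in cKO arch, 9.94% in cKO descending and 12.8% in control descending. At 1000 genes and 5% mitochondrial UMIs, moved medians were the contractile list -0.21 and the modulated list 1.16 in the arch and the contractile list 0.082 in the descending aorta. At 1000 genes and 5% mitochondrial UMIs, signs turned in the arch for the receptor list -0.040 and in the descending aorta for Ttn 0.60, Sln -1.24 and Actc1 -0.87. At 200 genes and 20% mitochondrial UMIs, smooth muscle-like shares were 13.2% in cKO arch, 37.8% in control arch, 24.3% in cKO descending and 21.8% in control descending, while phagocyte-like shares were 14.8% in cKO arch and 9.39% in control descending. At 200 genes and 20% mitochondrial UMIs, moved medians were the contractile list -0.22 in the arch and the modulated list 1.18 in the difference of differences. At 200 genes and 20% mitochondrial UMIs, signs turned in the descending aorta for the receptor list -0.0065 and Ttn 0.70 and between control regions for the modulated list -0.041, the chondrogenic list -0.19 and Hey1 -0.20. After thinning cells to 3000 UMIs, moved medians were the contractile list -0.067 and the modulated list 0.79 in the arch and the contractile list 0.14 in the descending aorta. After thinning cells to 3000 UMIs, signs turned in the arch for the chondrogenic list -0.26 and the receptor list -0.039, in the descending aorta for Ttn 0.40 and Cilp2 0.15, between control regions for the anterior Hox list -0.13, between cKO regions for Adm -0.095 and in the difference of differences for Plau -0.28 and Hoxa2 0.66. Without cells holding a UMI of another class's markers, moved medians were the contractile list -0.081 and the modulated list 0.76 in the arch, the contractile list 0.13 in the descending aorta and the modulated list 0.59 in the difference of differences. Without cells holding a UMI of another class's markers, signs turned in the arch for the chondrogenic list -0.19 and the receptor list -0.0075, in the descending aorta for the chondrogenic list -0.20, the anterior Hox list -0.027, Ttn 0.63, Fbln1 0.013 and Sln -0.074, between control regions for the anterior Hox list -0.035, between cKO regions for Chac1 -0.40 and Adm -0.43 and in the difference of differences for Hey1 0.22, Egln3 0.46 and Hbb-bs -0.70. Keeping the doublets, smooth muscle-like shares were 13.98% in cKO arch, while phagocyte-like shares were 20.6% in cKO arch, 4.71% in control arch and 11.7% in control descending. Keeping the doublets, moved medians were the contractile list -0.086 and the modulated list 0.78 in the arch and the modulated list 0.31 in the difference of differences. Keeping the doublets, signs turned in the arch for the chondrogenic list -0.17 and the receptor list -0.011 and in the descending aorta for Cilp 0.26. Requiring 100 UMIs of list members, signs turned in the arch for the chondrogenic list -0.35 and the receptor list -0.27 and between control regions for the modulated list -0.040 and the outflow tract list -0.061. Averaging over cells, moved medians were the contractile list -0.056 and the modulated list 0.75 in the arch and the contractile list 0.14 and the modulated list -0.083 in the descending aorta. Averaging over cells, signs turned in the arch for the chondrogenic list -0.19 and the receptor list -0.068, in the descending aorta for the anterior Hox list -0.036 and between control regions for the modulated list -0.047 and the anterior Hox list -0.043. Median-of-ratios scaling gave the contractile list -0.013 and the modulated list 1.10 in the arch and the contractile list 0.14 in the descending aorta. Without a minimum for list members, moved medians were the posterior Hox list -4.49 between control regions and the posterior Hox list -2.46 between cKO regions. Without a minimum for list members, signs turned in the descending aorta for the chondrogenic list -0.073. A prior of 5 UMIs gave the posterior Hox list -4.44 between control regions and the posterior Hox list -2.75 between cKO regions. At Leiden resolution 0.5, smooth muscle-like shares were 23.8% in cKO arch, 42.4% in control arch, 30.5% in cKO descending and 29.6% in control descending, while phagocyte-like shares were 25.5% in cKO arch and 11.6% in control descending. At Leiden resolution 0.5, moved medians were the contractile list -0.20 and the modulated list 1.12 in the arch and the modulated list 1.14 in the difference of differences. At Leiden resolution 0.5, signs turned in the arch for Egr3 0.45, between control regions for Fst -0.50 and in the difference of differences for Egr3 1.01. A total without mitochondrial, ribosomal protein and haemoglobin genes gave the contractile list -0.096 in the arch and the contractile list 0.12 in the descending aorta. In subclustering at resolution 1, the share of cells in subclusters mostly of their own library was 91.2% for the control arch and 7.79% for the control descending library, and without immediate early, mitochondrial and ribosomal protein genes it was 51.8% for the cKO descending library.

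Under settings chosen after seeing the data, the values were these. Under the automatic doublet threshold, phagocyte-like shares were 21.7% in cKO arch, 4.55% in control arch and 12.2% in control descending. Under the automatic doublet threshold, moved medians were the modulated list 1.34 in the difference of differences. Under the automatic doublet threshold, signs turned in the descending aorta for Ctss 0.13, Sln -0.25 and Actc1 -0.042. Within cluster 0 alone, moved medians were the modulated list 0.35 in the arch, the modulated list -0.071 in the descending aorta and the posterior Hox list -4.20 between control regions. In cluster 0, the sign in the arch turned for the chondrogenic list -0.11, the immediate early list 0.28, the receptor list -0.38, Ccn4 -0.0096, Tgfbi -0.33, Thbs1 -1.25, Timp1 -0.15, Nr4a2 0.029, Ankrd1 -0.26 and Hoxb6 -0.13. In cluster 0, the sign in the descending aorta turned for the contractile list -0.022, the anterior Hox list -0.036, the receptor list -0.18, Bche 0.56, Ttn 0.79, Cytl1 -0.059, Cilp 1.95, Cilp2 0.43 and Cacna1h -0.58. In cluster 0, the sign between control regions turned for the anterior Hox list -0.054, the outflow tract list -0.011, Casq2 2.77, Mfap2 -0.31, Tgfbi 0.90, Thbs1 0.45, Hspa1b -0.38 and Ankrd1 2.10. In cluster 0, the sign between cKO regions turned for the protease list -0.010, Egr2 -0.12, Nkx2-3 1.62 and Mfap5 0.48. In cluster 0, the sign in the difference of differences turned for the modulated list -0.32, the ion channel list 0.020, Fbln2 -0.32, Plau -0.61, Thbs1 -1.18, Ankrd1 -1.72, Hoxb5 -0.37 and Tbx5 2.65. Taking only RFP-high cells of the cKO arch library, moved medians were the contractile list -0.085 in the arch and the posterior Hox list -3.81 between cKO regions. Taking only RFP-high cells of the cKO arch library, signs turned in the arch for the chondrogenic list -1.11, the immediate early list 0.11 and Hoxb6 -0.31, between cKO regions for the protease list -0.020, the BMP target list -0.18 and Pln 0.23 and in the difference of differences for the TGF-beta target list -0.068, Id2 -0.20 and Hoxb5 -0.76. Taking only RFP-low cells of the cKO arch library, moved medians were the contractile list -0.15 in the arch. Taking only RFP-low cells of the cKO arch library, signs turned in the arch for the receptor list -0.16 and in the difference of differences for Pln -0.081. Adding cluster 31, moved medians were the contractile list -0.058 in the arch. Adding cluster 31, signs turned in the arch for the chondrogenic list -0.85 and between control regions for Prg4 0.060. Adding clusters 2, 4 and 31, moved medians were the contractile list -0.87 and the modulated list 3.77 in the arch and the modulated list 3.38 in the difference of differences. Adding clusters 2, 4 and 31, signs turned in the arch for the heritable disease list 0.031, a Ccl19 copy 0.12, Cilp 0.34 and Egr3 0.28, in the descending aorta for the inflammatory list 0.0020, between control regions for Prg4 0.29, between cKO regions for Col27a1 0.44 and Mfap5 0.37 and in the difference of differences for a Ccl19 copy 0.050 and Egr3 0.86. Between RFP-high and RFP-low cells, a boundary of 8 UMIs gave Smad4 -0.40 and the BMP target list -0.38 in smooth muscle-like cells and -0.89 in cluster 2. In cluster 2 the BMP target list was -0.83 with RFP per 10000 UMIs and -0.83 after thinning, and among cells with a Hand2 UMI it was -0.90, with Smad4 at -0.43. In smooth muscle-like cells of cluster 0 the BMP target list was -1.05.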

Other observations

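The tests named in this part were chosen only after the result was seen. In the control arch library, fibroblast-like cells hold a cluster found in no other library (cluster 17, 166 cells, 9.62% of the class), and thymocyte-like cells make up 3.23% of kept cells there and at most 0.268% elsewhere. The cKO arch library holds cluster 6, with 224 cells (4.00%) and none elsewhere. It scored 5.19 for macrophage markers but stayed unnamed, with the platelet marker Ppbp among its leading genes. Cluster 16, led by cycling genes such as Mki67, scored 5.335 for macrophage markers and held 285 cKO arch and 32 control arch cells. Both lie outside the phagocyte-like class, so its shares and values leave these cells out. In the control descending library adipocyte-like cells were 1.17% of kept cells against 0.464% in the cKO descending library, and Ucp1 and Car3 were higher in its smooth muscle-like droplets.

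Y-linked transcripts occur in 1 library only. Ddx3y had 1239 UMIs, Eif2s3y 945, Uty 302 and Kdm5d 229 in the control arch library and 0 in the other 3 libraries. Xist stood at 646 CPM in the cKO arch, 304 in the control arch, 462 in the cKO descending and 410 in the control descending library, so Xist and Y-linked transcripts occur together in the control arch library.

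A few other genes differed strongly between libraries. Rnaset2b in smooth muscle-like cells was 32.6, 61.2, 3.43 and 34.1 CPM in the cKO arch, control arch, cKO descending and control descending library. In that order Cwc22 was 14.3, 102, 189 and 125 CPM, Stbd1 202, 68.5, 127 and 25.1, and its chromosome 5 neighbour Scarb2 149, 106, 166 and 90.7. Vwc2 was 104, 20.1, 94.0 and 0.0602 CPM and Gabra3 80.8, 21.3, 83.0 and 0.421, so both were higher in each cKO library than in its control.

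In phagocyte-like cells of control mice, Ifit2 (5.57) and Ifit3 (3.82) were higher in the arch than in the descending aorta. Cluster 35 holds 0.306% of the control arch and 23.6% of the control descending phagocyte-like cells, so the make-up of the class also differs. In smooth muscle-like cells the clock spread of the cKO arch against the control arch library was -5.53. In RFP-high cells as a whole, 51.8% belonged to cluster 2, 32.2% to smooth muscle-like and 8.61% to fibroblast-like cells.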
